A study of Mus musculus with 17 samples.

How the data were processed

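Gene expression was measured by polyA RNA sequencing (TruSeq RNA V2 kit, RNA from Trizol and RNeasy columns, per the labels) in mouse limb buds of embryonic day 12.5. The labels list 17 samples, of which 15 have a column in the gene tables used here: 4 wild-type (WT) samples, 2 of Dup-C, 2 of Dup-L, 4 of Dup-LΔBor, 2 heterozygous (het) and 1 homozygous (hom) for ΔBor. Dup-C and Dup-L are duplications at the Sox9-Kcnj locus of chromosome 11, and ΔBor is a deletion of a domain boundary there. The other 2 samples, fingertips of embryonic day 17.5, are not analysed here, and the alternatives planned for them were not run. The labels do not give the zygosity of Dup-C, Dup-L or Dup-LΔBor, and they do not say whether replicates are separate embryos or which limb was taken. The p-values therefore measure the spread between these samples, which may be technical.

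The deposited count table holds raw counts per gene for 34682 genes, of which 10244 are 0 in all libraries. The authors aligned reads with STAR to mm9; DESeq2 and bedtools 2.17.0 are also named in their notes. The counting tool, its annotation and its strand setting are not given in the sources used here. A deposited table of the same genes and libraries holds FPKM values made by the authors, rounded to 2 decimals, with a library scale that is not given in the sources used here. Gene names were used as the files give them. In the table, 1781 names end in a copy suffix, and 1997 genes with any count have the same counts as another gene in every library. Reads of such genes may be shared, or genes with few counts may match by coincidence, which was not tested. No gene past a threshold had counts identical to another's. Chromosomes, neighbour order, GC content and transcript length were taken by symbol from an annotation of GRCm38, another build, so no coordinates are given. It gave a chromosome to 90.5% of the genes tested, and GC content and length to 91.4%.

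Samples were matched to columns by genotype and replicate. The Dup-LΔBor columns carry another genotype string, which joins a duplication and a deletion, and replicate names R2 to R5 where the labels number 1 to 4, so no column could be matched to a label. These libraries keep the column names and count as unpaired replicates. The ΔBor hom column is named R3 where its label gives replicate 1. The column headers hold library numbers in 2 ranges: WT 1 and 2, Dup-C, Dup-L and ΔBor fall in the first, and WT 3 and 4 with Dup-LΔBor in the second. These ranges are called the first and the second batch here. The R4 and R5 headers hold the same library number, but their counts differed as much as those of other replicates (mean chi-square per gene 31.6, against 7.08 to 41.5 for other Dup-LΔBor pairs).

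Counts were modelled in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr by group, robust quasi-likelihood F-test, two-sided). All 15 libraries entered 1 fit with 6 groups and no block, which tested 17655 genes. The p-values were adjusted by Benjamini-Hochberg over these genes, with a threshold of 0.05, and an adjusted p of a gene is from this fit unless a batch, offsets, a covariate, an omitted library, another alternative or another tool is named with it. A gene "rose", "fell" or "changed" only where it passed that threshold. Comparisons were Dup-C, Dup-L, Dup-LΔBor, ΔBor het and ΔBor hom each against WT, Dup-LΔBor against Dup-L, and Dup-C against Dup-L. Fold changes are log2, with a standard error (SE) from the F-statistic, and levels are counts scaled to library size (CPM, mean ± SD). ΔBor hom has 1 library, which is assumed to vary like the other groups. Where a group had no counts, a bound on the fold was computed against 3 counts per library, and such bounds cover counting error only.

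Gene lists were tested with camera from limma 3.58.1, with its preset correlation of 0.01 and, as an alternative, an estimated correlation, adjusted by Benjamini-Hochberg over 23 lists per comparison. The lists were the Sox9-Kcnj locus, flanking genes of chromosome 11, cartilage, hypertrophic cartilage and bone, joint interzone, tendon, distal limb, proximal limb, anterior-posterior patterning, hindlimb, apical ridge and limb signalling, surface ectoderm and epidermis, nail and hair keratinization, skeletal muscle, erythroid blood, endothelium, macrophage and immune, nerve and glia, cell cycle, immediate early and heat shock, hypoxia and glycolysis, histone genes and sex-linked genes. The forelimb list (Tbx5) and the mitochondrially encoded list had too few tested members for camera. Another 5 lists were written after the data were seen: maternally and paternally expressed genes of the Dlk1-Dio3 cluster, imprinted genes elsewhere, cytosolic ribosomal proteins, and the nuclear-encoded respiratory chain. They were adjusted among themselves. Beside the members of a list past the threshold over all genes stands the number adjusted over the list alone. That number was 0 where a list named for a comparison has no member past the threshold and none given. Lists not named for a comparison are not covered by this.

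Tests, comparisons, lists and the rule for named genes were fixed before the data were examined. For each comparison the rule named the genes of the Sox9-Kcnj locus list, flanking genes of chromosome 11 past the threshold, and up to 4 list members per direction past it. It also named, in each direction, up to 8 genes with the largest fold change among those past the threshold with at least 1 CPM in the higher group and no overlap between the libraries of both groups. This gave 377 values. The text gives examples of them, picked after their values were seen, while their dependence on the processing was computed for all 377. Results of 2 genes are not reported here, and these genes were left out of the outlier test of single libraries. Members of the added lists and limb type genes outside the rule were also chosen after their values were seen.

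Alternatives chosen before seeing the data were DESeq2 1.42.0 (its own size factors and independent filter), RLE factors in edgeR, no count filter, a fit of only the 2 groups compared, a replicate block, Xist as a covariate, ΔBor het and hom pooled, leaving out each library in turn, and limma on log2 FPKM. That last fit used genes with at least 0.5 FPKM in 2 libraries, with 1 or 0.1 added before the logarithm, or no filter. Alternatives chosen after seeing the data were the batch as a term in the fit, a fit within the batch of the mutant, per-library offsets for GC content and transcript length (natural splines with 5 degrees of freedom, 16133 genes), the batch with these offsets, camera with the batch, and Pitx1 as a covariate. The median of all genes moved by less than 0.1 log2 under every other scaling.

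Total counts per library ran from 3.45e7 to 5.37e7. In simulated counts with 200 changed genes among 17655 and the dispersions of these data, the edgeR fit recovered 77.6%, 86.6%, 92.5%, 71.6% and 64.2% of genes changed 2-fold in the comparisons of Dup-C, Dup-L, Dup-LΔBor, ΔBor het and ΔBor hom with WT. It recovered 82.1% for Dup-LΔBor against Dup-L and 74.6% for Dup-C against Dup-L, with 3 to 10 false calls per comparison. Changed genes were drawn only from those above a minimum expected count. The simulated libraries had no batch, GC, limb type or sex difference shared across genes, so these rates do not carry over to the real comparisons. In the Dup-LΔBor simulation, 36 of 224 DESeq2 calls and 13 of 191 limma calls on FPKM were false. A simulated GC trend in Dup-L gave 6397 calls among 15891 genes, and 0 with the offsets. That trend was a function of the same GC values that the offsets fit, and was alike in both Dup-L libraries. Its removal thus does not show how the offsets treat real changes that go with GC content. Among 20 simulated lists, camera found the raised list and 0 of the other 19. Genes were simulated independently there, so this does not show how camera behaves where members of a list vary together.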

Results

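RNA was sequenced from E12.5 mouse limb buds of wild-type (WT) embryos and of mutants with duplications or a boundary deletion at the locus of Sox9, a transcription factor of cartilage, and its neighbours Kcnj2 and Kcnj16, which encode inward-rectifier potassium channels. WT had 4 libraries with total counts of 5.27e7, 5.34e7, 5.37e7 and 3.45e7. Dup-C had 2 (5.20e7 and 3.89e7), Dup-L 2 (3.61e7 and 3.65e7), Dup-LΔBor 4 (R2 to R5 with 4.74e7, 3.71e7, 4.89e7 and 3.71e7), ΔBor het 2 (3.86e7 and 3.80e7) and ΔBor hom 1 (3.79e7). The series asks how duplications that keep or cross domain boundaries, and loss of a boundary, alter the genes around them.

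The libraries differed in genes that mark limb type. Pitx1, which specifies hindlimb, stood at 59.8 and 70.1 CPM in WT 1 and WT 3 but at 1.83 CPM in both WT 2 and WT 4. It was at 0.518 and 0.677 CPM in Dup-L and between 39.9 and 116 CPM in all Dup-C, Dup-LΔBor and ΔBor libraries. Tbx4, another hindlimb regulator, followed the same order, with 18.8 and 19.6 CPM in Dup-L, 25.8 and 27.6 CPM in WT 2 and WT 4, and 62.2 CPM or more elsewhere. Tbx5, the forelimb regulator, was at 186 and 184 CPM in Dup-L, at 233 and 191 CPM in WT 2 and WT 4, and between 86.2 and 136 CPM elsewhere. The labels say only limb buds, so no library was left out or regrouped on this account. Every comparison with Dup-L therefore sets libraries low in Pitx1 against libraries of which some or all were high. In every other comparison with WT, all mutant libraries were high in Pitx1, while WT 2 and WT 4 were low. Xist, expressed from the inactive X chromosome, was at 2265 CPM in WT 1, 2586 CPM in Dup-C 1 and 2870 CPM in ΔBor hom, and at 1.34 CPM or less in the other 12 libraries. The sex-linked list had 0 of 4 tested members past the threshold in each of the 7 comparisons. This does not show that sex was balanced, since Xist varied widely within WT and Dup-C and the only ΔBor hom library was high.

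**Figure D1:**
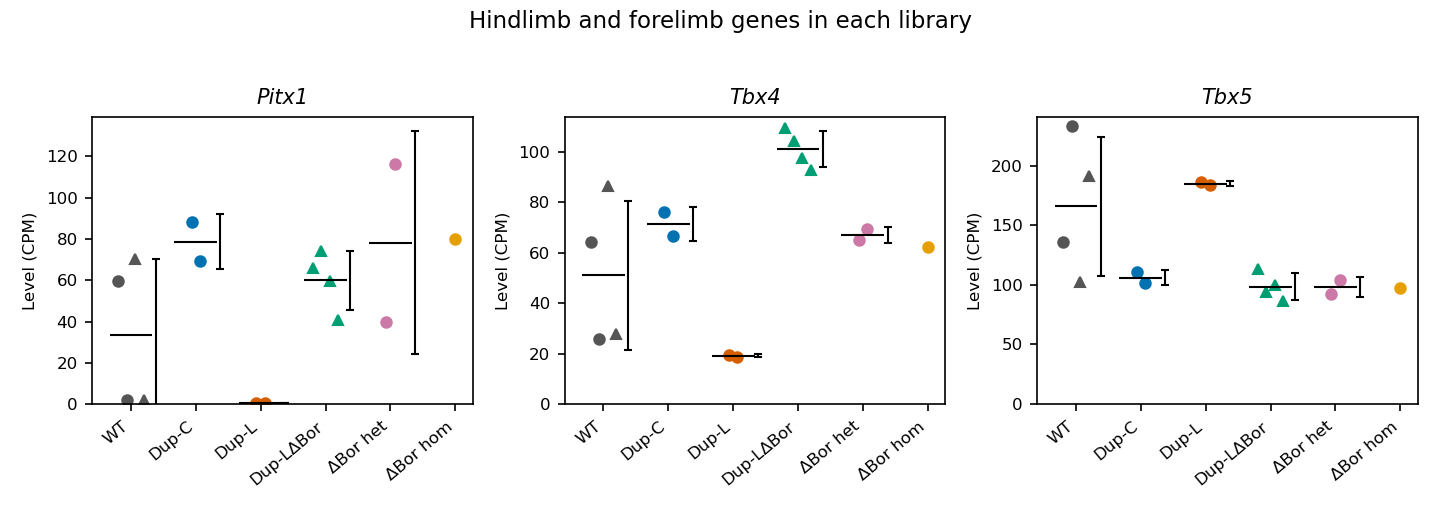
CPM of Pitx1, Tbx4 and Tbx5 in each of the 15 libraries by group, with circles for the first batch of library numbers and triangles for the second, lines for group means and bars for 1 SD where a group has more than 1 library. Both Dup-L libraries and 2 of the 4 WT libraries lie at 1.83 CPM of Pitx1 or less, and all others at 39.9 CPM or more.

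Fold changes also followed the GC content of the genes. In Dup-L against WT, the median log2 fold change over 5 equal bins of GC content, from low to high, was 0.45, 0.19, -0.02, -0.25 and -0.52. GC content and transcript length together explained 59.2% of the variance of log2 fold changes among 12180 genes in that comparison, 36.5% in ΔBor het, 31.2% in ΔBor hom, 14.7% in Dup-C and 2.80% in Dup-LΔBor, each against WT. They explained 45.2% in Dup-LΔBor against Dup-L and 30.9% in Dup-C against Dup-L.

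**Figure D2:**
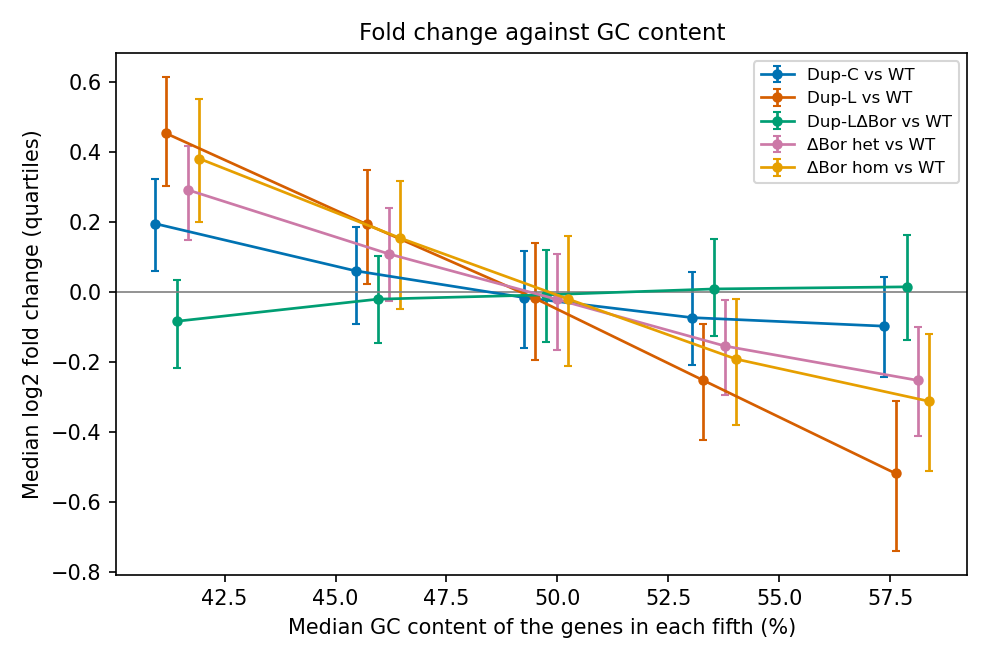
Median log2 fold change of the genes in each of 5 equal bins of GC content, plotted at its median GC content in percent, for the 5 comparisons with WT, with bars from the lower to the upper quartile and points set slightly apart. The Dup-L line falls from 0.45 to -0.52, and the Dup-LΔBor line stays within 0.1 of 0.

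Whether the Dup-C duplication changes expression at the locus was asked by comparing Dup-C with WT. Kcnj2 rose, with a log2 fold change of 1.89 (SE 0.18, adjusted p = 7.2e-04), from 21.9 ± 3.51 CPM in WT (n = 4) to 81.5 ± 8.86 CPM in Dup-C (n = 2). Its level was 87.7 and 75.2 CPM in the Dup-C libraries and 26.2, 21.7, 22.2 and 17.6 CPM in WT 1 to 4. Sox9 stood at 158 ± 22.7 CPM against 146 ± 18.9 CPM in WT, a log2 fold change of 0.11 (SE 0.14, adjusted p = 0.695). Kcnj16 had 0 to 3 counts in each of the 15 libraries and was not tested in any comparison, so a loss or a small change of it was not detectable at this depth. Of the other locus genes, the noncoding RNA 2610035D17Rik was at 0.53 (adjusted p = 0.251), BC006965 at -1.31 (adjusted p = 0.251), the kinase gene Map2k6 at 0.30 (adjusted p = 0.257) and the zinc transporter gene Slc39a11 at -0.02 (adjusted p = 0.947). With the batch as a term Kcnj2 was at 1.77 (adjusted p = 0.0401), and within the first batch, where 2 libraries stand on each side, at 1.76 (adjusted p = 0.124). Over all edgeR and limma alternatives its log2 fold change ran from 1.62 to 1.99 and its adjusted p from 3.4e-04 to 0.269.

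**Figure D3:**
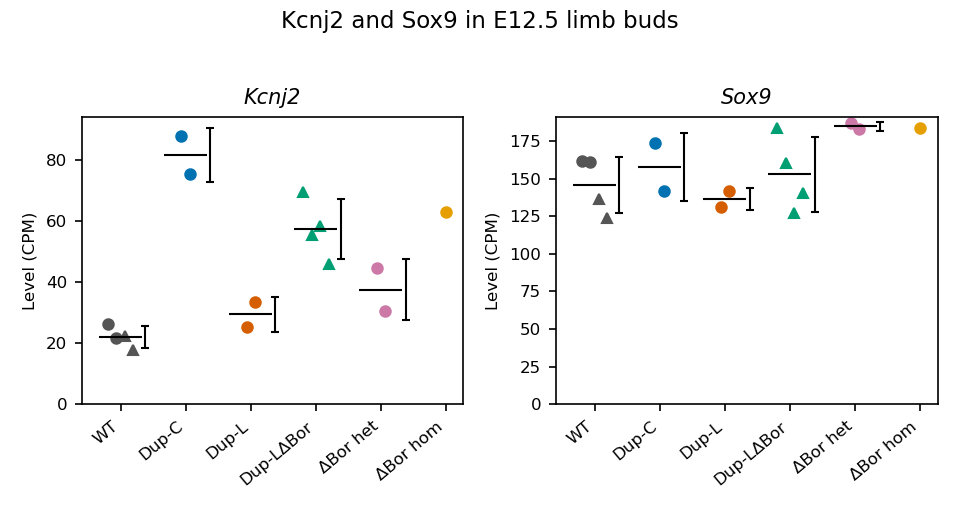
CPM of Kcnj2 and Sox9 in each of the 15 libraries by group, with circles for the first batch of library numbers and triangles for the second, lines for group means and bars for 1 SD where a group has more than 1 library. All 4 WT libraries lie between 17.6 and 26.2 CPM of Kcnj2 and both Dup-C libraries at 75.2 CPM or more, while group means of Sox9 lie between 137 and 185 CPM.

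In the Sox9-Kcnj locus list 1 of 6 tested members rose in Dup-C (4 adjusted over the list alone), with a camera adjusted p = 0.024 and an adjusted p = 0.487 with an estimated correlation. The cartilage list, with Sox9, Col2a1 and Acan, had 0 of 20 members past the threshold, a median log2 fold change of -0.60 and a camera adjusted p of 3.9e-05, or 0.491 with an estimated correlation. Hypertrophic cartilage and bone (0 of 13, 4 adjusted over the list alone, median -0.64, 7.7e-05 or 0.487), tendon (0 of 11, 5 adjusted over the list alone, median -0.55, 5.9e-05 or 0.487), joint interzone (0 of 13, median -0.43, 0.0011 or 0.490), skeletal muscle (0 of 23, median -0.64, 1.7e-04 or 0.616) and endothelium (0 of 14, median -0.30, 5.9e-05 or 0.487) were also lower by camera. Erythroid blood (0 of 12, median 0.69, 3.4e-05 or 0.487), the hindlimb list (0 of 7, median 1.02, 0.0011 or 0.490), distal limb (0 of 17, median 0.31, 0.0056 or 0.491) and cell cycle (0 of 20, median 0.12, 0.0159 or 0.616) were higher. With the batch as a term 9 of these 11 lists passed, and distal limb (0.195) and the locus list (0.0552) did not. The batch term does not take out limb type. WT 1 and 2 of the first batch differ in Pitx1, as do WT 3 and 4 of the second, while both Dup-C libraries were high. No list was tested with Pitx1 as a covariate in any comparison, so these list changes cannot be told apart from limb type.

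Across 17655 genes the Dup-C comparison gave 1 gene past the threshold, Kcnj2, while 2933 genes had an unadjusted p under 0.05. Leaving out WT 1 gave 1640 genes, and leaving out any of the other 5 libraries kept the count at 1. Within the first batch 0 genes passed in edgeR (608 with an unadjusted p under 0.05), as with the batch and GC offsets together (570). DESeq2 gave 23 genes, 15 of them higher, but its filter gave an adjusted p to only 1734 genes and Kcnj2 was not among them. Adjusted over all genes with a p, DESeq2 gave 7 genes, and Kcnj2 (log2 fold change 1.89) had an adjusted p of 1.2e-17. On FPKM, limma gave 1 gene with either pseudocount and 3 with no filter.

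For Dup-L, the comparison with WT asks what a duplication of Sox9 locus sequence does alone. Both Dup-L libraries were low in Pitx1, as were WT 2 and WT 4, so the duplication cannot be told apart from limb type here. Genes of hindlimb identity fell: Pitx1 (log2 fold change -5.80, adjusted p = 0.0482), Tbx4 (-1.41, adjusted p = 0.0248), Hoxc11 (-1.99, adjusted p = 0.0147) and Hoxc12 (adjusted p = 0.00313). Several patterning genes also fell, among them Lmx1b, which sets dorsal identity (-1.13, SE 0.17, adjusted p = 0.00138), Tbx2 (-1.03, SE 0.19, adjusted p = 0.00192), Msx1 of the distal mesenchyme (-1.73, adjusted p = 0.00849) and the hedgehog effector Gli2 (-0.63, adjusted p = 0.00342). The growth factor gene Ptn rose (1.81, adjusted p = 0.0346), as did mitochondrially encoded mt-Nd4 (0.76, adjusted p = 0.00577). Within the first batch Pitx1 (adjusted p = 0.147), Tbx4 (adjusted p = 0.0594) and Msx1 (-1.78) did not pass, while Hoxc11, Hoxc12, Lmx1b, Tbx2, Gli2, Ptn and mt-Nd4 did. Of these 7, Lmx1b alone passed with GC and length offsets (-0.60, adjusted p = 0.0148), where Tbx2 was at -0.19, Gli2 at -0.061 and mt-Nd4 at 0.00057. Hoxc11 (-1.68, adjusted p = 0.0909), Hoxc12 (-0.74, adjusted p = 0.0781) and Ptn (1.47, adjusted p = 0.129) kept larger folds there without passing. With the offsets and the batch Gli2 (0.0062) and mt-Nd4 (-0.046) took the opposite sign. Kcnj2 stood at 29.3 ± 5.75 CPM (n = 2) against 21.9 ± 3.51 CPM, a log2 fold change of 0.42 (SE 0.19, adjusted p = 0.104) that was -0.01 with GC and length offsets. Sox9 was at 137 ± 7.39 CPM, or -0.09 (SE 0.14, adjusted p = 0.657).

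At the locus, 2610035D17Rik rose in Dup-L (0.46, adjusted p = 0.0427) but did not pass within the batch (0.28, adjusted p = 0.247), while Map2k6 (0.12), Slc39a11 (0.02) and BC006965 (-0.14) did not pass. Among 16 flanking genes of chromosome 11, Abca5 (0.94, adjusted p = 0.00267) and Abca8b (0.54) rose, and Cog1, which acts in Golgi transport (-2.24, adjusted p = 0.00201), Cdc42ep4 (-0.37, but 0.13 with GC and length offsets) and Sdk2 (-0.98) fell. That list had 5 members past the threshold adjusted over the list alone and a camera adjusted p of 0.680. For the locus list, with 1 of 6 past the threshold (0 adjusted over the list alone), the camera adjusted p was 0.649.

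None of the 23 lists passed camera in Dup-L, and the lowest adjusted p was 0.168 (0.857 with an estimated correlation), shared by 5 lists. These were the hindlimb list (4 of 7 fell, 4 adjusted over the list alone), surface ectoderm (1 rose and 6 fell of 18, 7 adjusted over the list alone), endothelium (1 rose and 6 fell of 14, 7 adjusted over the list alone), immediate early and heat shock genes (5 fell of 15, 6 adjusted over the list alone) and erythroid blood (2 fell of 12, 1 adjusted over the list alone). In endothelium, Plvap (-1.04) and Sox18 (-1.02) fell, and Emcn rose (0.42, but -0.11 with GC and length offsets). Nerve and glia had 3 members that rose and 5 that fell of 13 (8 adjusted over the list alone), cell cycle 1 and 6 of 20 (8 adjusted over the list alone, with falls of Mcm2 by 0.80 and Plk1 by 0.82), and distal limb and anterior-posterior patterning 1 and 5 of 17 each (6 each adjusted over the list alone). In the cartilage list 1 of 20 members fell (0 adjusted over the list alone), Col2a1 (-0.79, adjusted p = 0.0328), which stood at 0.03 with GC and length offsets, and Col1a1 of the bone list fell by 1.01. Tendon (2 rose and 1 fell of 11), proximal limb (2 rose of 13), the apical ridge (4 fell of 20), nail and hair (1 rose and 3 fell of 14) and histone genes (3 fell of 10) were mixed or partial, with 2, 1, 1, 4 and 3 adjusted over the list alone. Joint interzone (1 fell of 13), skeletal muscle (1 of 23), macrophages (1 of 15) and hypoxia and glycolysis (1 of 19, Pfkl by 1.08) had a single member past the threshold, and 0, 1, 0 and 1 adjusted over the list alone. Of the added lists, 30 of 52 ribosomal protein genes fell (32 adjusted over the list alone, camera adjusted p = 1.5e-08, 0.512 with an estimated correlation), and 25 of 48 respiratory chain genes fell and 3 rose (33 adjusted over the list alone, 5.4e-06 or 0.512).

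In all, 5719 genes passed in Dup-L against WT, 2797 higher and 2922 lower, of which 616 changed at least 2-fold. The count was 4187 with the batch as a term and 3036 within the first batch (1126 higher, 1910 lower). With GC and length offsets 844 genes passed (299 higher, 545 lower), 573 of them among the 5719, with these offsets and the batch 145 (25 higher, 120 lower), and with Pitx1 as a covariate 0 in edgeR, with 4722 genes at an unadjusted p under 0.05. Without a count filter 5219 genes passed, 1968 of them higher. DESeq2 gave 6207 genes and limma on FPKM 5840. Leaving out Dup-L 1 gave 2740 genes and leaving out Dup-L 2 gave 1122. Of the 88 named genes past the threshold, 80 lost it without Dup-L 2, 45 without Dup-L 1, 19 without WT 3, 12 without WT 1, 12 without WT 4 and 8 without WT 2. The 8 that kept it whichever library was left out were Lmx1b, Tbx2, Plk1, Mcm2, Ier2, Mrps34, Hist1h4d and Mir692-1.

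What Dup-L together with the boundary deletion does was asked by comparing Dup-LΔBor with WT, 4 libraries against 4. Kcnj2 rose by 1.38 on the log2 scale (SE 0.16, adjusted p = 5.2e-04), to 57.2 ± 9.77 CPM from 21.9 ± 3.51 CPM, and kept this under every alternative and with every library left out. Within the second batch its log2 fold change was 1.52 (adjusted p = 0.00548, range over all alternatives up to 0.0117). Sox9 was at 153 ± 24.8 CPM, or 0.07 (SE 0.12, adjusted p = 0.765), and 2610035D17Rik rose (0.57, adjusted p = 0.0363) but was at 0.74 (adjusted p = 0.066) within the batch. Map2k6 (0.14), Slc39a11 (-0.15) and BC006965 (-1.13, adjusted p = 0.0591) did not pass, and Abca8b was the only flanking gene of 16 that changed (0.59, adjusted p = 0.0275, 2 adjusted over the list alone). Largest of all were the falls of noncoding RNAs transcribed from the maternal copy of the imprinted Dlk1-Dio3 cluster of chromosome 12. Meg3 stood at 0.182 ± 0.0812 CPM against 501 ± 264 CPM, a log2 fold change of -11.46 (SE 0.58, adjusted p = 9.7e-07). Rian (-6.72, SE 0.31, adjusted p = 2.0e-07) and Mirg (-6.32, SE 0.36, adjusted p = 5.0e-07) fell too, and within the second batch Meg3 was at -11.55, Rian at -6.95 and Mirg at -6.53, each past the threshold.

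**Figure D4:**
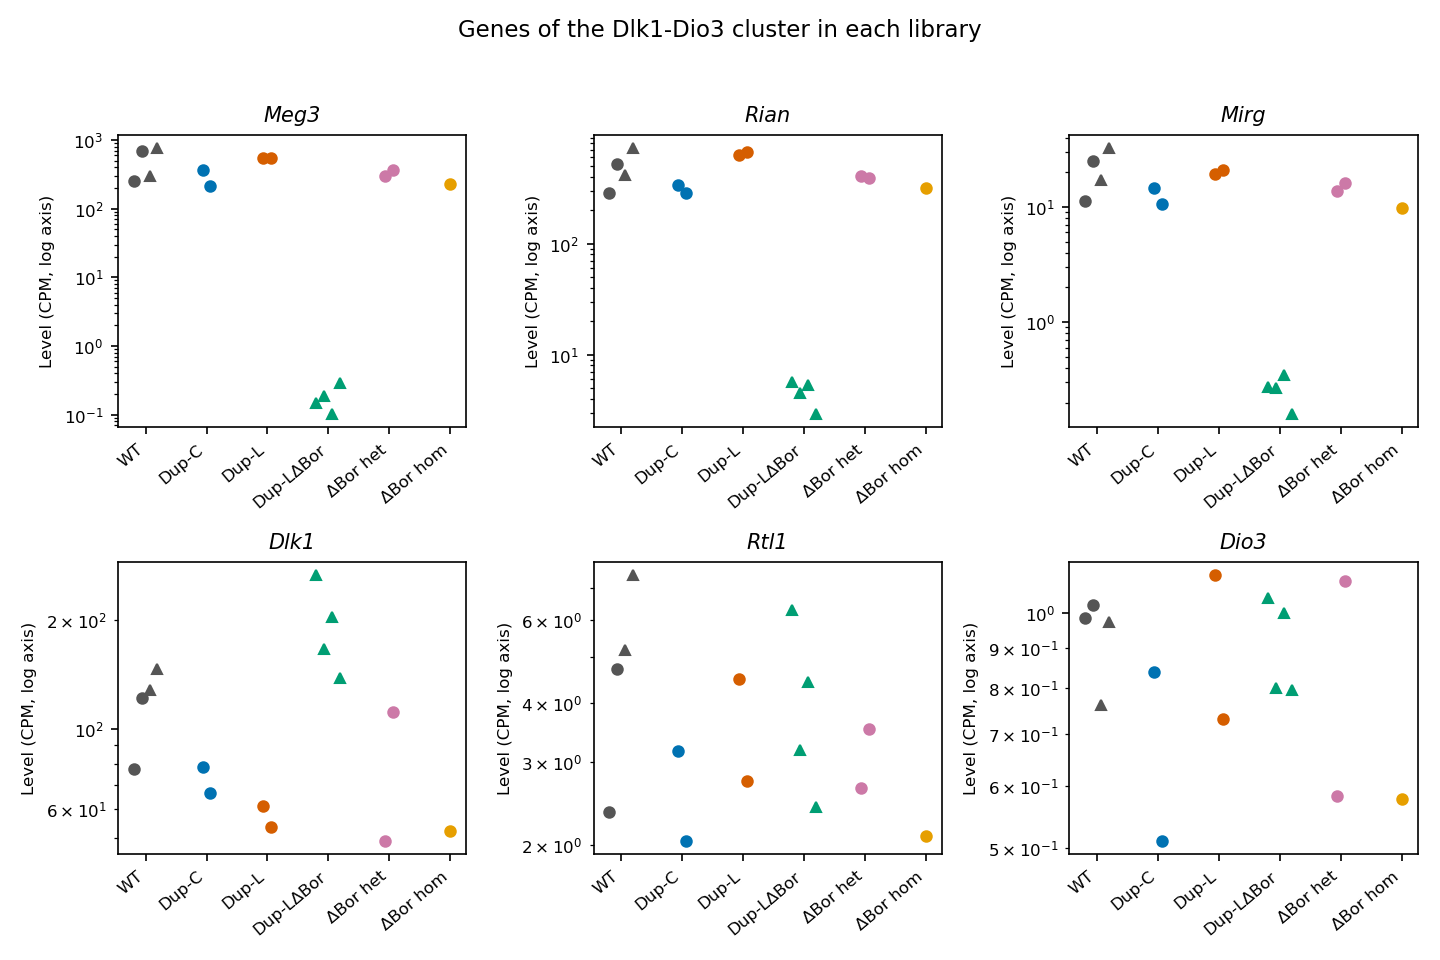
CPM on a log axis of 6 genes of the imprinted Dlk1-Dio3 cluster in each of the 15 libraries by group, with circles for the first batch of library numbers and triangles for the second. Meg3 lies between 0.102 and 0.292 CPM in the 4 Dup-LΔBor libraries and at 215 CPM or more in all others.

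All 4 tested maternally expressed genes of that cluster fell (4 adjusted over the list alone, camera adjusted p = 8.0e-13, 0.00345 with an estimated correlation), while 0 of 3 paternally expressed genes passed (camera adjusted p = 0.540), with Dlk1 at 0.71, Rtl1 at -0.26 and Dio3 at -0.03. Both lists, and that of imprinted genes elsewhere, were written after the data were seen, so their p-values are not independent support. Of 36 imprinted genes elsewhere, 6 rose and 1 fell (8 adjusted over the list alone, camera adjusted p = 0.286), and Igf2, a fetal growth factor gene, rose by 0.73 (adjusted p = 0.00731). Hypoxia and glycolysis genes rose in 8 of 19 cases (18 adjusted over the list alone, median log2 0.91, camera adjusted p = 2.8e-12, 0.459 with an estimated correlation and 1.3e-12 with the batch). Among them were Eno1 (1.59, adjusted p = 0.0103), the phosphofructokinase genes Pfkl (1.07, adjusted p = 0.0103) and Pfkp (1.07, adjusted p = 0.0256), and Vegfa, which drives vessel growth (1.08, adjusted p = 0.0329). Within the second batch these 4 were at 1.47, 0.97, 1.02 and 1.10, with adjusted p of 0.194, 0.218, 0.356 and 0.329. R2 had the highest level of the 4 libraries, with 771 CPM of Pfkl (others 388 to 465 CPM), 331 CPM of Vegfa (142 to 219 CPM) and 496 CPM of Slc2a1 (193 to 247 CPM). Without R2, Eno1 (1.23, adjusted p = 0.015), Pfkl (0.80, adjusted p = 0.00311) and Pfkp (0.74, adjusted p = 0.0428) still passed, but Vegfa did not (0.80, adjusted p = 0.0529). Vegfa was also lost without R3, R5, WT 1 or WT 2 (adjusted p 0.0545 to 0.0811), and Pfkp without R5, WT 1 or WT 2 (0.0536 to 0.0656).

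**Figure D5:**
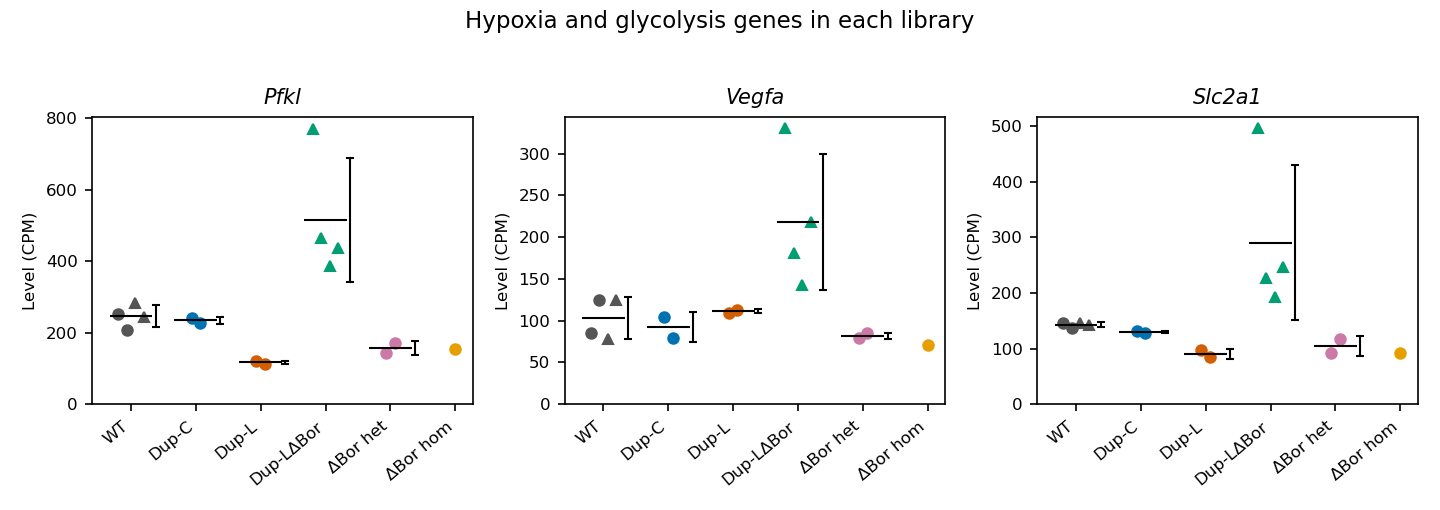
CPM of Pfkl, Vegfa and Slc2a1 in each of the 15 libraries by group, with circles for the first batch of library numbers and triangles for the second, lines for group means and bars for 1 SD where a group has more than 1 library. Pfkl averaged 515 CPM in Dup-LΔBor, 246 CPM in WT and 117 CPM in Dup-L.

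Foxd3 (-1.44, adjusted p = 0.019) and Sox10 (-0.84, adjusted p = 0.020), regulators of neural crest and glia, and Ngfr (-0.59, adjusted p = 0.0307) fell in Dup-LΔBor. In the nerve and glia list 4 of 13 members fell (4 adjusted over the list alone, camera adjusted p = 0.0463, 0.459 with an estimated correlation). Within the second batch Ngfr passed (adjusted p = 0.0152), and Foxd3 (adjusted p = 0.123) and Sox10 (adjusted p = 0.0654) did not. The apical ridge list had Dkk1 (-0.98) and En1 (-0.71) fall of 20 members (8 adjusted over the list alone, camera adjusted p = 0.00268 or 0.459). Nail and hair genes (0 of 14, 4 adjusted over the list alone, median -0.40, 0.0108 or 0.459) and macrophage genes (1 fell of 15, 5 adjusted over the list alone, 0.0297 or 0.459) were lower by camera. The other lists did not pass without the batch. All 5 that passed without it did so again in the fit with the batch, as did tendon (adjusted p = 0.00412), surface ectoderm (0.00692), muscle (0.0239) and the bone list (0.0241), which were lower, and distal limb (0.0109) and the locus list (0.0239), which were higher. None of these 6 passed with an estimated correlation (all at 0.638 or more, fit without the batch). Here too the batch term does not take out the difference in Pitx1 from WT 2 and WT 4. By single genes, without the batch, anterior-posterior patterning had 2 falls of 17 (Tbx3 by 0.71 and Alx4 by 0.60), surface ectoderm 1 fall of 18, histone genes 1 fall of 10, the bone list 1 rise of 13 (Spp1, 1.86), joint interzone 1 rise of 13, immediate early genes 1 rise of 15 and the locus list 2 rises of 6. In that order 4, 1, 2, 4, 1, 1 and 3 members passed when adjusted over the list alone. Cartilage (20 members), tendon (11), distal limb (17), proximal limb (13), hindlimb (7), muscle (23), erythroid blood (12), endothelium (14) and cell cycle (20) had 0 members past the threshold, and when adjusted over the list alone 2 of hindlimb, 1 of proximal limb and 1 of endothelium passed. The forelimb gene Tbx5 fell (-0.75, adjusted p = 0.0494) but was at -0.58 within the batch (adjusted p = 0.337). Its level was 86.2 to 113 CPM in Dup-LΔBor and 136 and 102 CPM in WT 1 and WT 3. In WT 2 and WT 4, which were low in Pitx1, it was 233 and 191 CPM.

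Dup-LΔBor differed from WT in 679 genes, 397 higher and 282 lower, with 144 changed at least 2-fold. The count was 70 with the batch as a term (30 higher, 40 lower), 66 within the second batch and 1179 with GC and length offsets. DESeq2 gave 1656 genes (794 higher, 862 lower), RLE factors 705 (384 higher, 321 lower), and limma on FPKM 651 (247 higher, 404 lower) or, with the smaller pseudocount, 630 (210 higher, 420 lower). Leaving out WT 1, 2, 3 or 4 gave 322, 180, 1087 or 1516 genes, and leaving out R2, R3, R4 or R5 gave 157, 81, 174 or 313. Of 37 named genes past the threshold, 12 lost it without WT 1, 20 without WT 2, 2 without WT 3, 1 without WT 4, 17 without R2, 22 without R3, 15 without R4 and 15 without R5. Kcnj2, Meg3, Rian, Mirg, Pfkl, Eno1 and Hist2h2be were among the 14 that kept it, and Vegfa, Pfkp, Foxd3, Sox10, Ngfr, Spp1, Tbx5 and 2610035D17Rik were not.

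The boundary deletion on its own was compared with WT in het and hom embryos. In ΔBor het, Kcnj2 rose by 0.77 on the log2 scale (SE 0.19, adjusted p = 0.043), to 37.5 ± 9.96 CPM (n = 2), but was at 0.63 within the first batch (adjusted p = 0.285). It lost the threshold without WT 3 (0.77), WT 4 (0.69) or ΔBor het 1 (0.47, adjusted p = 0.603, the highest of all alternatives). With GC and length offsets it was at 0.48 (adjusted p = 0.209), and at 0.42 with the batch as well (adjusted p = 0.582). Sox9 was at 185 ± 3.03 CPM, or 0.34 (SE 0.14, adjusted p = 0.143), with Map2k6 at 0.17, Slc39a11 at 0.15, 2610035D17Rik at -0.17 and BC006965 at -0.49, none past the threshold. The largest changes lay on chromosome 7. Klk1b22, a kallikrein gene, had no counts in WT and 2.46 and 1.88 CPM in the 2 ΔBor het libraries, at least 26.1-fold higher. Lgals7, a galectin of stratified epithelia (-3.05, SE 0.29, adjusted p = 1.2e-04), the amino acid transporter gene Slc1a5 (-1.63, SE 0.11, adjusted p = 2.1e-06) and the vomeronasal receptor gene Vmn2r29 (-2.85, SE 0.30, adjusted p = 3.3e-04) fell, and stood at -2.68, -1.70 and -2.77 within the first batch, each still past the threshold.

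Keratin genes of the surface also fell in ΔBor het, namely Krt14 (-0.70, adjusted p = 0.0388), Krt17 (-0.71) and Krt16 (-0.94). Krt14 and Sfn were the 2 of 18 surface ectoderm members that fell (2 adjusted over the list alone, camera adjusted p = 0.162), and Krt16 and Krt17 the 2 of 14 in the nail and hair list (4 adjusted over the list alone, camera adjusted p = 0.309). None of these 4 passed within the first batch. Of 13 nerve and glia members 2 fell (Tubb3 by 0.93 and Ngfr by 0.68), of 10 histone genes 1 fell, and of 17 distal limb members 1 rose (Bmp2, 0.47), with 2, 1 and 2 adjusted over the list alone. None of the 23 lists passed camera in ΔBor het, the lowest adjusted p being 0.162 (0.926 with an estimated correlation). Of the added lists, 7 of 52 ribosomal protein genes fell (11 adjusted over the list alone, camera adjusted p = 9.5e-04, 0.480 with an estimated correlation), and of 48 respiratory chain genes 8 fell and 1 rose (23 adjusted over the list alone, 0.00152 or 0.480).

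Against WT, 712 genes passed in ΔBor het, 398 higher and 314 lower. The count was 32 with the batch as a term, 55 within the first batch, 83 with GC and length offsets and 9 in a fit of the 2 groups alone. DESeq2 gave 2162 genes and limma on FPKM 579, or 102 with no filter. Leaving out WT 1, WT 3, WT 4, ΔBor het 1 or ΔBor het 2 gave 2490, 205, 56, 19 or 1929 genes. Of 25 named genes past the threshold, 18 lost it without ΔBor het 1, 17 without WT 4, 9 without WT 3, 4 without ΔBor het 2 and 2 without WT 2. Klk1b22, Lgals7, Slc1a5, Vmn2r29 and Arhgap33os were among the 7 that kept it whichever library was left out, and Krt14, Krt16, Krt17, Tubb3, Ngfr and Bmp2 were not.

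In ΔBor hom, with 1 library, Kcnj2 was at 63.0 CPM and rose by 1.52 (SE 0.22, adjusted p = 0.010), but was at 1.35 within the first batch (adjusted p = 0.0872), and its adjusted p over all alternatives reached 0.214. Sox9 was at 183 CPM, or 0.33 (SE 0.18, adjusted p = 0.254), and Map2k6 (0.34), Slc39a11 (0.02), 2610035D17Rik (0.11) and BC006965 (-0.24) did not pass. Klk1b22 was again present only in the ΔBor libraries, at 5.07 CPM in ΔBor hom, at least 60.8-fold higher than in WT. Lgals7 (adjusted p = 0.00167) and Vmn2r29 (-2.59, adjusted p = 0.0107) fell, as did the exchanger gene Slc8a2 of chromosome 7 (-1.77, adjusted p = 0.0162). Hand1, a transcription factor of the ventral limb (-3.14), Krt14 (-0.96), Krt16 (-1.13) and Ngfr (-1.15) also fell, the first 3 with an adjusted p of 0.0489 and Ngfr with 0.0444, and none of them passed within the first batch. Within that batch Lgals7 did pass (-2.87, adjusted p = 0.0064), but Vmn2r29 (adjusted p = 0.0845) and Slc8a2 (adjusted p = 0.154) did not. Of genes tested with a chromosome, 7.71% lay on chromosome 7, against 12.6% of those that changed in ΔBor het and 13.5% in ΔBor hom, and within the first batch 33.3% and 30.0%.

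By camera, 8 lists passed in ΔBor hom, and 0 with an estimated correlation. Skeletal muscle was lower (0 of 23 past, median -1.14, adjusted p = 2.0e-04, 0.620 with an estimated correlation), as were endothelium (0 of 14, 3 adjusted over the list alone, 0.00558 or 0.620), macrophages (0 of 15, 4 adjusted over the list alone, 0.0203 or 0.620), joint interzone (0 of 13, 0.0272 or 0.620), tendon (0 of 11, 1 adjusted over the list alone, 0.0272 or 0.620) and surface ectoderm (1 fell of 18, 4 adjusted over the list alone, 0.0343 or 0.624). Distal limb (0 of 17, 0.0203 or 0.620) and erythroid blood (0 of 12, 0.0125 or 0.620) were higher. With the batch as a term, muscle, erythroid blood, endothelium and macrophages passed, but that term does not take out the difference in Pitx1 from WT 2 and WT 4. Nail and hair (1 fell of 14, 2 adjusted over the list alone) and nerve and glia (1 fell of 13, 6 adjusted over the list alone) did not pass camera. In total 225 genes passed, 159 higher and 66 lower, with 71 changed at least 2-fold, against 26 with the batch as a term, 26 within the first batch, 15 with GC and length offsets (9 higher, 6 lower) and 3 in a fit of the 2 groups alone. DESeq2 gave 2196 genes (1334 higher, 862 lower) limma on FPKM 42 (22 higher, 20 lower) or, with the smaller pseudocount, 62 (22 higher, 40 lower), and edgeR without a count filter 114 (69 higher, 45 lower). Leaving out WT 1, 2, 3 or 4 gave 2750, 76, 114 or 21 genes. Without WT 2, 3 or 4, 9, 7 or 11 of 20 named genes lost the threshold, but Kcnj2, Klk1b22, Lgals7, Vmn2r29 and Slc8a2 kept it each time and Hand1, Krt14, Krt16 and Ngfr did not.

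Kcnj2 was also compared between the mutants, with adjusted p-values over all genes. Dup-LΔBor exceeded Dup-L by 0.96 (SE 0.20, adjusted p = 0.0015) and ΔBor het was lower than Dup-LΔBor by a log2 fold change of -0.61 (SE 0.19, adjusted p = 0.0269). Dup-LΔBor against Dup-C was at -0.51 (SE 0.18, adjusted p = 0.0593). Dup-LΔBor shares no batch with these 3 groups, so genotype and batch are told apart only through WT. In the fit with the batch, ΔBor het was at -0.87 against Dup-LΔBor (SE 0.29, adjusted p = 0.133), which did not pass, and Dup-LΔBor at -0.25 against Dup-C (SE 0.29, adjusted p = 0.795). ΔBor hom against het, both of the first batch, was at 0.75 (SE 0.26). It did not pass over all genes, which does not show that het and hom are alike, since hom has 1 library. The change of Kcnj2 in Dup-LΔBor was tested against the sum of those in Dup-L and ΔBor. It differed by 0.19 (SE 0.27, adjusted p = 0.592) with ΔBor het and by -0.56 (SE 0.30, adjusted p = 0.159) with ΔBor hom. These values were 0.58 (SE 0.42, adjusted p = 0.366) and -0.17 (SE 0.45, adjusted p = 0.828) with the batch as a term. Sox9 passed in none of the 15 pairs of groups, the lowest adjusted p being 0.143, or 0.107 with the batch. Its unadjusted edgeR p was 0.0288 in ΔBor het against WT (0.202 with the batch). In ΔBor het against Dup-L it was 0.0190 (0.00956 with the batch). No other pair was under 0.05 unadjusted in the fit without the batch.

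What the boundary deletion adds to Dup-L was asked by comparing Dup-LΔBor with Dup-L, groups that share no batch, so no value within a batch could be had. Kcnj2 rose by 0.96 (57.2 ± 9.77 CPM against 29.3 ± 5.75 CPM), and by 1.22 with the batch as a term (adjusted p = 0.0232). It did not pass with Pitx1 as a covariate (0.64, SE 0.33, adjusted p = 0.212). Sox9 was at 0.16 (SE 0.14, adjusted p = 0.387). BC006965 fell (-0.99, adjusted p = 0.0449), but was at -0.75 with the batch (adjusted p = 0.415), and Map2k6 (0.01), Slc39a11 (-0.17) and 2610035D17Rik (0.11) did not pass. Meg3 (-11.60), Rian (-7.13) and the X-linked Xlr3b (-6.61, adjusted p = 1.2e-04) fell, as did the RNA DQ267102 of chromosome 12, at least 14.9-fold. Among genes of limb identity Pitx1 (6.64, adjusted p = 0.0231) and Tbx4 (2.40, adjusted p = 0.00129) rose and Tbx5 fell (-0.91, adjusted p = 0.00629). With the batch as a term these stood at 6.40 (adjusted p = 0.132), 2.05 (adjusted p = 0.0597) and -0.58 (adjusted p = 0.292). Lmx1b (1.15, adjusted p = 1.6e-04), Tbx2 (1.12, adjusted p = 3.6e-04) and Bmp7 (1.62, adjusted p = 5.1e-04) rose, and the mesenchymal growth factor gene Fgf10 fell (-0.86, adjusted p = 7.8e-04), each past the threshold with the batch too. The batch term does not correct for GC content and transcript length, which explained 45.2% of the variance in this comparison. With offsets for both, Lmx1b was at -0.60 and Tbx2 at -0.19 in Dup-L against WT.

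Hypoxia and glycolysis genes rose in 13 of 19 cases between Dup-L and Dup-LΔBor (13 adjusted over the list alone, median 0.97, camera adjusted p = 0.00213, 0.865 with an estimated correlation), with Pfkl at 2.14 (adjusted p = 6.6e-05) and the glucose transporter gene Slc2a1 at 1.68 (adjusted p = 9.9e-04). The other 22 lists did not pass camera. Among them endothelium had 7 rises and 1 fall of 14 (11 adjusted over the list alone, camera adjusted p = 0.216), cell cycle 6 and 5 of 20, immediate early and heat shock genes 6 rises of 15, distal limb 5 rises and 1 fall of 17, and the bone list 2 rises and 5 falls of 13, the last 4 with 11, 6, 5 and 7 adjusted over the list alone. Cartilage had 2 rises, Fgfr3 (1.03) and Col2a1 (1.01), and 1 fall, Hapln1 (-0.84), of 20 (3 adjusted over the list alone). All 4 maternally expressed Dlk1-Dio3 genes fell (4 adjusted over the list alone, camera adjusted p = 1.3e-05, 0.0505 with an estimated correlation). This list, like the ribosomal and respiratory ones that follow, was written after the data were seen, so its p-values are not independent support. Ribosomal protein genes rose in 29 and fell in 7 of 52 cases (37 adjusted over the list alone, 1.7e-05 or 0.455), and respiratory chain genes rose in 21 and fell in 10 of 48 (31 adjusted over the list alone, 0.0156 or 0.508).

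This comparison gave 7704 genes, 3794 higher and 3910 lower, with 1713 changed at least 2-fold. With the batch as a term 2298 passed, with GC and length offsets 4478, with both 194, and with Pitx1 as a covariate 1390. DESeq2 gave 7826 genes and limma on FPKM 7366. Without Dup-L 1 the count was 4943 and without Dup-L 2 it was 4438. Of 108 named genes past the threshold, 32 lost it without Dup-L 1, 43 without Dup-L 2, and 14, 11, 11 and 9 without R2, R3, R4 and R5. Kcnj2, Meg3, Rian, Tbx4, Tbx5, Lmx1b, Tbx2, Bmp7, Fgf10, Pfkl and Slc2a1 were among the 57 that kept it each time, and Pitx1 and Col2a1, lost without either Dup-L library, were not.

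Dup-C and Dup-L, both of the first batch, were compared to test how the duplications differ from each other. Kcnj2 was higher in Dup-C by 1.47 (SE 0.22, adjusted p = 0.00906), and also with the first batch alone (adjusted p = 0.0176). Sox9 was at 0.21 (SE 0.17, adjusted p = 0.410), with Map2k6 at 0.18, Slc39a11 at -0.04, 2610035D17Rik at 0.08 and BC006965 at -1.17, none past the threshold. Hindlimb genes were higher in Dup-C, among them Pitx1 (7.03, adjusted p = 0.0499), Hoxc11 (3.04, adjusted p = 0.0109) and Tbx4 (1.90, adjusted p = 0.0244), and with the first batch alone Pitx1 had an adjusted p of 0.106. The apical ridge signal Fgf8 (2.67, adjusted p = 0.0121) and the embryonic globin gene Hba-x (1.65, adjusted p = 0.0134) were higher too. Dcn (-1.32, adjusted p = 0.0233) and Kera (-1.15, adjusted p = 0.0169), matrix genes of tendon, and Phex of mineralising bone (-2.43, adjusted p = 0.0247) were lower. Mmrn1, a vessel and platelet gene, had no counts in either Dup-C library, at least 151-fold lower than in Dup-L, and also none in WT 1.

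The hindlimb list rose in 6 of 7 members (6 adjusted over the list alone, camera adjusted p = 0.00115, 0.720 with an estimated correlation), erythroid blood in 4 of 12 (10 adjusted over the list alone, 2.1e-05 or 0.720), distal limb in 6 of 17 (7 adjusted over the list alone, 0.00378 or 0.720), the apical ridge in 5 of 20 (11 adjusted over the list alone, 0.0344 or 0.720), cell cycle in 5 of 20 (5 adjusted over the list alone, 0.0189 or 0.720) and surface ectoderm in 3 of 18 (5 adjusted over the list alone, 0.0424 or 0.720). Tendon fell in 4 of 11 (9 adjusted over the list alone, 0.00687 or 0.720), and cartilage was lower by camera with 0 of 20 past the threshold (0.0424 or 0.750). Ribosomal protein genes rose in 32 of 52 cases (36 adjusted over the list alone, 4.2e-19 or 0.143) and respiratory chain genes in 24 of 48 (32 adjusted over the list alone, 1.0e-13 or 0.143). These 2 lists were written after the data were seen. In all, 2674 genes passed, 1728 higher and 946 lower, with 568 changed at least 2-fold. Within the first batch 2659 passed, with GC and length offsets 197 (152 higher, 45 lower), without a count filter 2392 (1888 higher, 504 lower), with DESeq2 3589 and with limma on FPKM 2565. With Pitx1 as a covariate 0 passed in edgeR, with 650 genes at an unadjusted p under 0.05. Leaving out Dup-C 1, Dup-C 2, Dup-L 1 or Dup-L 2 gave 0 genes in edgeR, with 4395, 4057, 4080 or 3577 at an unadjusted p under 0.05. All 65 named genes past the threshold, Kcnj2 and Pitx1 included, lost it whichever of these 4 libraries was left out.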

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

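The outlier test of single libraries was set before the data were seen, while the tests for chromosome 7 and the test of Meg3 against the batch were chosen after their results were seen. The clauses that decide the cell type lists and the paternally expressed genes were also set after their results.

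In 9 of 274 groups of 4 libraries, 1 library lay apart from the other 3, relative to the range of the 4. Chance alone does so in about 1 in 20 groups, so the flags are no more frequent than that. A small gap can be flagged where the other 3 lie close together, as in Hist1h2bc below. Dcn, a matrix gene of tendon, was at 30.5 CPM in WT 1 and between 51.7 and 53.0 CPM in the other WT libraries, and Hand2 was at 142 CPM in WT 1 and between 105 and 111 CPM in the others. Msx1 was at 38.2 CPM in WT 4 (others 40.5 to 41.0 CPM). Among the Dup-LΔBor libraries, R2 was apart in Gabrd (0.459 CPM, others 1.47 to 1.54 CPM) and Sulf1 (505 CPM, others 564 to 570 CPM). R4 was apart in Hist1h2bc (1.32 CPM, others 1.27 to 1.28 CPM) and Hist1h3a (0.998 CPM, others 1.23 to 1.27 CPM), and R5 in Hoxa11as (3.24 CPM, others 2.10 to 2.25 CPM) and the tendon regulator Scx (32.0 CPM, others 39.2 to 40.5 CPM). No explanation of these single values was tested.

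A first pattern is the 5719 genes past the threshold in Dup-L against WT. An effect of the duplication itself was looked for in Dup-LΔBor, which carries it too. Of 3854 genes past the threshold in Dup-L against WT 1 and 2, only 46.4% went the same way in Dup-LΔBor against WT 3 and 4. That met the bound set against this cause but does not decide it. Dup-L and Dup-LΔBor also differ in Pitx1, in the trend with GC content and in the boundary deletion, any of which could hide a shared effect. Bias by GC content and transcript length stays open. With offsets for both, 573 of the 5719 genes (10.02%) still passed, just above the 10% set as the bound for this cause. Only 5453 of the 5719 could be tested with the offsets. Over these 5453 the median fold on the log2 scale went from 0.55 (median SE 0.13) to 0.18 (median SE 0.11). Among them calls thus ended because the folds shrank and not because the errors grew. More or fewer cells of another type could not be told apart either: the lowest camera adjusted p over 6 lists was 0.168, which met the bound set against it, yet 8 of 13 nerve and glia members and 7 of 14 endothelial members passed, in both directions, so the list test decides nothing. A different share of forelimb and hindlimb was not excluded either. Pitx1 and Tbx4 were lower and Tbx5 higher in Dup-L than in WT 1 and WT 3, and the same held for WT 2 and WT 4. The limb type genes thus go with such a difference, but how many of the 5719 genes it accounts for was not settled. With Pitx1 as a covariate 0 genes passed in edgeR (4722 with an unadjusted p under 0.05), but this decides nothing. The median fold of the 5719 genes on the log2 scale went only from 0.56 (median SE 0.13) to 0.44 (median SE 0.17), and 3803 of them still had an unadjusted p under 0.05.

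A second pattern is the excess of chromosome 7 among the genes changed in ΔBor, with Klk1b22, Lgals7, Slc1a5 and Vmn2r29 among them. A difference between the batches is argued against, since within the first batch alone the share on chromosome 7 was at least 3.92 times that of tested genes in both het and hom. A stretch of chromosome 7 from another strain fits: the 15 genes past the threshold with the batch as a term spanned 686 of 1232 tested genes, and 0.21% of 10000 random sets spanned as few (median 1099). That test was written after the genes were seen and says nothing of the strain, and no genotypes were analysed here. Loss of the boundary by itself is argued against by Dup-LΔBor, which lacks it too. In edgeR 0 of the 15 genes passed there the same way, with or without the batch, and 1 passed the opposite way without it. At an unadjusted p under 0.05 with the batch, 1 went the same way and 4 the opposite. The median ratio of their log2 fold change to that in ΔBor was -0.0384 (quartiles -0.23 and 0.022). An effect of the boundary that the duplication offsets was not tested, and the zygosity of Dup-LΔBor is not given.

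The last pattern is the loss of Meg3, Rian and Mirg in Dup-LΔBor. A difference between the batches is argued against, since the lower Meg3 level of WT 3 and 4 was 1016 times the highest of Dup-LΔBor. Altered imprinting of the cluster cannot be told apart from other causes: the median log2 fold change of the paternally expressed Dlk1, Rtl1 and Dio3 was -0.033, under the bound set against it, but the bound was wrong for members that go both ways (Dlk1 0.71, Rtl1 -0.26). Altered imprinting of many genes stays open too, as 11.1% of 36 imprinted genes elsewhere passed with the batch as a term, between the bounds set for either answer. In that fit 70 of all 17655 genes passed, a much smaller share, though the list was written after the data were seen. Chance division of the libraries does not account for the comparison with WT, since of the 35 ways to divide the 8 libraries into 4 and 4 only 1, the real one, gave as many as 114 genes, and the highest other gave 3. These fits had no batch term. All 4 Dup-LΔBor libraries but only WT 3 and 4 are of the second batch, so the divisions do not tell genotype from batch.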

How the results depend on the processing

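Alternatives with the batch, GC and length offsets or Pitx1 were chosen after the data were seen, as were the 5 added lists. Across all alternatives, 4814 gene values kept their direction and side of the threshold, 2203 kept only their direction, 9 came past the threshold and 106 turned. RLE factors left 374 of 377 values the same and DESeq2 354 of 356, while with GC and length offsets 148 of 360 stayed the same and with the batch as well 87 of 360. Kcnj2 in Dup-LΔBor against WT passed under all 21 alternatives, with log2 fold changes of 1.13 to 1.53, and kept its direction in every other comparison but Dup-L against WT. Of 161 tests of gene lists, 33 passed camera, 32 with the batch and 0 with an estimated correlation. A loss or a small change of Kcnj16, with at most 3 counts in a library, is beyond the depth of these libraries, and a group of 1 library left after omission is assumed to vary like the others. Where a value turned, the cause was not tested.

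No paired fit is the reference, because only a number is shared. The deviations of same-numbered libraries from their group means had correlations from -0.16 to 0.14. In groups of 2 libraries these deviations mirror each other, so this check does not exclude a pairing. With the replicate block the count was 0 in Dup-C against WT, 1376 in Dup-L against WT, 36 in ΔBor het against WT, 20 in ΔBor hom against WT and 1460 in Dup-C against Dup-L. Sox9 (-0.0427) and Slc39a11 (0.0402) took the opposite sign in Dup-C against WT. In Dup-L against WT the sign turned for Map2k6 (-0.0461). ΔBor hom against WT had the opposite sign for 2610035D17Rik (-0.14). In edgeR with the block 403 genes had an unadjusted p under 0.05 in Dup-C against WT. No paired analysis was possible for Dup-LΔBor because its columns run from R2 to R5 and its labels from 1 to 4, so no column could be matched to a label.

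With DESeq2 the count was 23 in Dup-C against WT, 1656 in Dup-LΔBor against WT, 2162 in ΔBor het against WT and 2196 in ΔBor hom against WT. With no count filter the count was 114 in ΔBor hom against WT. Slc39a11 (-0.0481) took the opposite sign in Dup-L against WT. In ΔBor hom against WT the sign turned for Slc39a11 (-0.00107). Dup-C against Dup-L had the opposite sign for Slc39a11 (0.0234). With a fit of only the 2 groups the count was 114 in Dup-LΔBor against WT, 9 in ΔBor het against WT, 3 in ΔBor hom against WT and 5568 in Dup-C against Dup-L. With Xist as a covariate the count was 2 in Dup-C against WT, 162 in Dup-LΔBor against WT, 34 in ΔBor hom against WT and 723 in Dup-C against Dup-L. Slc39a11 (0.00165) took the opposite sign in Dup-C against WT. In ΔBor hom against WT the sign turned for 2610035D17Rik (-0.0816). Dup-C against Dup-L had the opposite sign for 2610035D17Rik (-0.0532). With limma on FPKM with 1 added the count was 42 in ΔBor hom against WT. Slc39a11 (-0.0108) took the opposite sign in Dup-L against WT. In ΔBor hom against WT the sign turned for Slc39a11 (-0.0371). Dup-LΔBor against Dup-L had the opposite sign for Map2k6 (-0.00103). With limma on FPKM with 0.1 added the count was 62 in ΔBor hom against WT. Slc39a11 (-0.0129) took the opposite sign in Dup-L against WT. In ΔBor hom against WT the sign turned for Slc39a11 (-0.0441). Dup-LΔBor against Dup-L had the opposite sign for Map2k6 (-0.00122). With limma on FPKM with no filter the count was 3 in Dup-C against WT, 210 in Dup-LΔBor against WT, 102 in ΔBor het against WT and 1547 in Dup-C against Dup-L. Slc39a11 (-0.0108) took the opposite sign in Dup-L against WT. In ΔBor hom against WT the sign turned for Slc39a11 (-0.0371). Dup-LΔBor against Dup-L had the opposite sign for Map2k6 (-0.00103). With ΔBor het and hom pooled the count was 3543 in ΔBor het against WT.

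With the batch as a term the count was 70 in Dup-LΔBor against WT, 32 in ΔBor het against WT, 26 in ΔBor hom against WT and 2298 in Dup-LΔBor against Dup-L. Sox9 (-0.0355) and Slc39a11 (0.0448) took the opposite sign in Dup-C against WT. In Dup-L against WT the sign turned for Map2k6 (-0.0184). ΔBor hom against WT had the opposite sign for 2610035D17Rik (-0.0430). Hoxa10 (0.0178), Tbx3 (0.0213) and Hoxc13 (0.0293) took the opposite sign in Dup-LΔBor against Dup-L. With a fit within the batch the count was 0 in Dup-C against WT, 3036 in Dup-L against WT, 66 in Dup-LΔBor against WT, 55 in ΔBor het against WT and 26 in ΔBor hom against WT. In Dup-C against WT the sign turned for Sox9 (-0.0396) and Slc39a11 (0.0401). Dup-L against WT had the opposite sign for Map2k6 (-0.0478). 2610035D17Rik (-0.0905) took the opposite sign in ΔBor hom against WT. In edgeR within the batch 608 genes had an unadjusted p under 0.05 in Dup-C against WT.

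With GC and length offsets the count was 844 in Dup-L against WT, 1179 in Dup-LΔBor against WT, 83 in ΔBor het against WT, 15 in ΔBor hom against WT, 4478 in Dup-LΔBor against Dup-L and 197 in Dup-C against Dup-L. In Dup-C against WT the sign turned for Slc39a11 (0.0735). Dup-L against WT had the opposite sign for Kcnj2 (-0.0102), Map2k6 (-0.0721), Cdc42ep4 (0.13), Col2a1 (0.0305), Lor (0.0295), Wls (-0.15), Emcn (-0.11) and Sox10 (0.15). 2610035D17Rik (-0.0638), Prkar1a (0.0534), Gli2 (-0.0355), Hand2 (-0.0747) and Emcn (0.17) took the opposite sign in Dup-LΔBor against Dup-L. In Dup-C against Dup-L the sign turned for 2610035D17Rik (-0.0778). With the batch and the offsets together the count was 0 in Dup-C against WT, 145 in Dup-L against WT, 139 in Dup-LΔBor against WT, 26 in ΔBor het against WT, 16 in ΔBor hom against WT, 194 in Dup-LΔBor against Dup-L and 1263 in Dup-C against Dup-L. Dup-C against WT had the opposite sign for Slc39a11 (0.11). Kcnj2 (-0.0768), Map2k6 (-0.22), Pth1r (0.14), Scx (0.0123), Gli2 (0.00616), Lor (0.46), Wls (-0.11), Cldn5 (0.00703), Csf1r (0.0939), Sox10 (0.18), Bub1 (-0.0292), E2f1 (0.0592) and mt-Nd4 (-0.0459) took the opposite sign in Dup-L against WT. In ΔBor het against WT the sign turned for Map2k6 (-0.0594). Dup-LΔBor against Dup-L had the opposite sign for Sdk2 (-0.12), Prkar1a (0.0958), Pth1r (-0.26), Scx (-0.14), Hoxd13 (0.12), Hoxd10 (0.25), Gli2 (-0.17), Tie1 (-0.26), Elavl4 (0.17), Bub1 (0.11) and Rrm2 (0.25). 2610035D17Rik (-0.0775) took the opposite sign in Dup-C against Dup-L. In edgeR with both, 570 genes had an unadjusted p under 0.05 in Dup-C against WT.

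With Pitx1 as a covariate the count was 0 in Dup-L against WT, 1371 in Dup-LΔBor against WT, 1117 in ΔBor het against WT, 130 in ΔBor hom against WT, 1390 in Dup-LΔBor against Dup-L and 0 in Dup-C against Dup-L. In ΔBor het against WT the sign turned for BC006965 (0.28). ΔBor hom against WT had the opposite sign for BC006965 (0.59). Map2k6 (-0.22), BC006965 (0.59), Mef2c (0.10), Hoxd10 (0.0443) and Tbx5 (0.0472) took the opposite sign in Dup-LΔBor against Dup-L. In Dup-C against Dup-L the sign turned for Map2k6 (-0.0689), BC006965 (0.51), Gchfr (-0.17), Hoxc10 (-0.51), Tbx4 (-0.0662), Wnt3 (-0.0785) and Car2 (-0.0903). In edgeR with Pitx1, 4722 genes had an unadjusted p under 0.05 in Dup-L against WT and 650 in Dup-C against Dup-L.

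Leaving out each library in turn gave counts of 1 to 1640 in Dup-C against WT, 1122 to 5952 in Dup-L against WT, 81 to 1516 in Dup-LΔBor against WT, 19 to 2490 in ΔBor het against WT, 21 to 2750 in ΔBor hom against WT, 4438 to 7671 in Dup-LΔBor against Dup-L and 0 throughout in Dup-C against Dup-L. With libraries left out, Dup-C against WT had both signs for Sox9 (-0.0429 to 0.25) and Slc39a11 (-0.0454 to 0.0139). Both signs were seen in Dup-L against WT for Slc39a11 (-0.0362 to 0.0858) and BC006965 (-0.46 to 0.14). With libraries left out, Dup-LΔBor against WT had both signs for Sox9 (-0.0356 to 0.15). Both signs were seen in ΔBor het against WT for 2610035D17Rik (-0.38 to 0.000110). With libraries left out, ΔBor hom against WT had both signs for Slc39a11 (-0.00695 to 0.0547), 2610035D17Rik (-0.0190 to 0.20) and BC006965 (-0.47 to 0.0511). Both signs were seen in Dup-LΔBor against Dup-L for Map2k6 (-0.0151 to 0.0733) and 2610035D17Rik (-0.00850 to 0.23). With libraries left out, Dup-C against Dup-L had both signs for Slc39a11 (-0.0840 to 0.0186) and 2610035D17Rik (-0.0869 to 0.22). In edgeR, 3577 to 4395 genes had an unadjusted p under 0.05 in Dup-C against Dup-L with a library left out.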

Other observations

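The lists and genes named here were chosen after the data were seen. Along the first principal component, with 35.5% of the variance, the Dup-LΔBor libraries lay at 39.8 or more, WT 1 to 4 at -13.8, 1.91, 22.0 and 25.2, Dup-C at -10.5 and -24.8, Dup-L at -35.3 and -38.1, ΔBor het at -42.9 and -20.6, and ΔBor hom at -38.5. 1700048O20Rik stood at 0.853 ± 0.159 CPM in Dup-LΔBor (n = 4), with 0.668 to 1.01 CPM in its libraries, and at 7.64 CPM or more in the other 11. Cytosolic ribosomal protein genes fell in 3 of 52 cases in Dup-LΔBor against WT and in 0 of 52 in ΔBor hom, and genes of the respiratory chain fell in 5 and 0 of 48. When adjusted over the list alone these numbers were 4, 0, 9 and 2. In Dup-LΔBor the respiratory chain was lower by camera (adjusted p = 0.0123, 8.7e-08 with the batch, 0.731 with an estimated correlation), and the ribosomal list only with the batch (0.540, 0.00899 with it, 0.875 with an estimated correlation). In ΔBor hom neither passed (0.363 each). In Dup-C against WT 0 of 52 and 0 of 48 members passed (0 and 8 adjusted over the list alone), with medians of 0.15 and 0.11, and by camera both lists were higher (2.5e-05 and 2.4e-04, and 0.362 each with an estimated correlation).

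The trend with GC content also differed between libraries of 1 genotype. The median log2 deviation of the highest minus that of the lowest of 5 bins was -0.60 in ΔBor het 1 and 0.029 in ΔBor het 2, and -0.42 in ΔBor hom. It was -0.67 and -0.75 in Dup-L, 0.14, 0.22, 0.41 and 0.27 in WT 1 to 4, 0.12 and -0.16 in Dup-C, and 0.51, 0.43, 0.37 and 0.12 in R2 to R5.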
